A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

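Total RNA of 2 diploid budding yeast strains was compared on 2 two-colour spotted arrays. The strains were BY4743, the wild type of the S288C background, and a homozygous fun30 deletion strain from the systematic deletion library. Both were grown in rich medium to exponential phase. Per the labels, 1 culture of each strain was split before RNA extraction, and each array received its own RNA preparations. The 2 arrays are therefore repeats of the extraction, labelling and hybridisation of the same pair of cultures. Their spread is technical, and p-values measure only that spread. RNA was copied with random primers and labelled with Cy3 or Cy5. The labels put the fun30 null RNA in Cy5 and the wild-type RNA in Cy3 on both arrays, so according to the labels no dyes were swapped. They list the null RNA as channel 2 on array 1 but as channel 1 on array 2.

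The scanner tables hold foreground and local background intensity of each spot in both dyes, which were quantified with GenePix Pro 5.0 without normalization, per the file headers. They also hold the percent of saturated pixels of each spot, per the file headers. A deposited table of log2 ratios gives the authors' processed values of the same spots, and how they were made is not given in the sources used here. Set against the scanner values, the deposited log2 ratios ran as Cy5 over Cy3 on both arrays, with Pearson r = 0.83 and 0.80 across spots. Their medians were 0.03 on both arrays, so they are centred, and the method of centring stays unknown. No other column of per-sample values was present.

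Each array had 13440 spots, of which 12500 were gene spots for 6250 open reading frame probes spotted in duplicate. The array also held 172 spots of probes whose names end in -R, 64 Arabidopsis control spots and 704 empty or unnamed spots. The software's bad or absent marks left out 1287 gene spots (10.3%) on array 1 and 2359 (18.9%) on array 2. Background was corrected with normexp and an offset of 50 on median foreground and median background. Ratios were normalized within each array by global loess, in which marked spots and control spots had weight 0. The unmarked duplicate spots of a probe were averaged. The -R probes stayed out of the gene table. A gene was tested if at least 1 of its spots exceeded the local background by 2 background SDs in at least 1 dye on each array, which left 5036 genes. Saturated spots were kept. Of the 6250 probes, 5763 matched a locus tag of the NCBI RefSeq gene table of assembly R64, 12 took their name from the array and 475 kept the systematic name. No build is named in the sources used here, so no coordinates are given.

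The 2 log2 ratios of each gene were tested against 0 with limma 3.58.1 (lmFit and eBayes, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment at 0.05 and 1 residual degree of freedom before moderation. Each SE given is limma's moderated SE, which draws a gene's spread toward that of all genes. It is not the SE of the gene's own 2 values. Gene lists, chromosomes and regions were tested with limma's camera at a preset inter-gene correlation of 0.01. An alternative estimated that correlation from the 2 arrays. It rests on 1 residual degree of freedom, so a list can hardly pass it. Its values therefore cannot show that correlation removed a call. The 35 gene lists, the tests, the rule for named genes and the first set of alternatives were chosen before the data were examined. Lists with at least 3 measured members were tested, which were 33. The alpha-cell and transposon lists had too few. The name pattern of the transposon list does not match Ty reading frames that carry only a systematic name, such as YMR046C. Measured Ty transcripts were therefore not tested as a set. List medians were set beside 10000 random lists of the same size matched on mean intensity in 10 bins. With no coordinates, the pericentromeric list holds the reading frames numbered 1 to 5 from the centromere on each arm, and the subtelomeric list the last 5 numbers of each arm.

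The deleted gene went against the labels on 1 array. Results are therefore described in 2 readings, one with the dyes as labelled on both arrays and one with the sign of array 2 turned. The planned rule named FUN30, its measured neighbours, the strain markers, the 12 highest and 12 lowest genes past the test with the same sign on both arrays, and up to 4 members of each list, of which 1 cell cycle result is not reported here. Directions with fewer than 12 such genes were filled with genes at least 1.5-fold the same way on both arrays, ranked by the smaller ratio and reported as not past the test. A gene not above background in 1 strain's channel on both arrays has only a lower bound of its fold. The bound was taken from channel values after loess and Aquantile normalization, and is open to dye bias.

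The scripts were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold among 5036. With the dyes as labelled, 75.0% of the 2-fold and 100% of the 4-fold genes were called, and 1.69% of calls were false. The simulated arrays shared no dye or probe effect, so 1.69% does not cover false calls that such an effect would give. With array 2 turned, 0% of either were called, because the Cy5 over Cy3 ratio that both arrays share then counts as spread. A count of 0 genes in that reading therefore says little about absent changes. A list of 40 genes shifted by 0.3 on the log2 scale was recovered in both readings. Simulated values were drawn independently for each array and gene, whereas the real arrays correlate at r = -0.72 once array 2 is turned. The simulation therefore does not show how often the set test calls lists falsely in that reading. Alternatives covered the background correction, the offset, the within-array and between-array normalization, the foreground statistic, the filter, the deposited values, the direction of array 2, each array alone, the moderation, the duplicate spots, the thresholds and the set tests. Figures were drawn with matplotlib.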

Results

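Transcript levels of a diploid budding yeast strain that lacks FUN30 were compared with those of its wild type on 2 arrays, each carrying both RNAs in different dyes. Fun30 is an ATPase of the Snf2 family of chromatin remodellers, known for roles in the resection of DNA ends and in silencing. The comparison asks which transcripts differ when it is absent in exponential growth in rich medium. Median foreground and background of gene spots were 425 and 116 in Cy5 and 1041 and 230 in Cy3 on array 1. On array 2 they were 454 and 194 in Cy5 and 748 and 259 in Cy3. Gene spots above background made up 69.5% in Cy5 and 77.4% in Cy3 on array 1, and 55.7% and 74.2% on array 2. Duplicate spots correlated across genes with r = 0.81 and 0.84. The number of arrays, 2 from 1 culture per strain, limits the precision of every value.

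FUN30 itself (YAL019W, chromosome I) followed the labels on array 1 and went against them on array 2. On array 1 its 2 spots read 121 and 184 in Cy5, labelled fun30 null, over backgrounds of 138 and 157, and 923 and 994 in Cy3, labelled wild type, over 260 and 294. On array 2 they read 392 and 762 in Cy5, again labelled fun30 null, over 234 and 226, and 434 and 330 in Cy3 over 305 and 252. Only 1 spot per array was above background, in Cy3 on array 1 and in Cy5 on array 2, and the other 2 spots in neither dye. The normalized log2 ratio of Cy5 to Cy3 was -1.82 on array 1 and 1.66 on array 2. Its mean with the dyes as labelled was -0.08 ± 0.70 (moderated SE, n = 2 arrays, limma adjusted p = 0.943). With array 2 turned it was -1.74 ± 0.39 (moderated SE, n = 2 arrays). That was the smallest unadjusted limma p of the 5036 genes (0.00125), and its adjusted p was 1.00. Array 2 was turned because of FUN30, so this rank restates its opposite ratios. In that reading FUN30 was above background only in wild-type channels, by 1 spot on each array, and at least 2.16-fold higher than in the null. Because the deleted gene contradicts the label of array 2, the text speaks of RNA labelled fun30 null and describes 2 readings in turn.

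Across genes the Cy5 to Cy3 ratios of the 2 arrays went together, with Pearson r = 0.72 and Spearman rho = 0.70 over 5036 genes, which are not independent replicates. When array 2 was turned, the same r was -0.72. The part of the ratios shared by both arrays in dye terms held 85.9% of their variance, and the part that changes sign between arrays 14.1%. FUN30 was in the second part, as were SCP1 and IMD2.

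**Figure D1:**
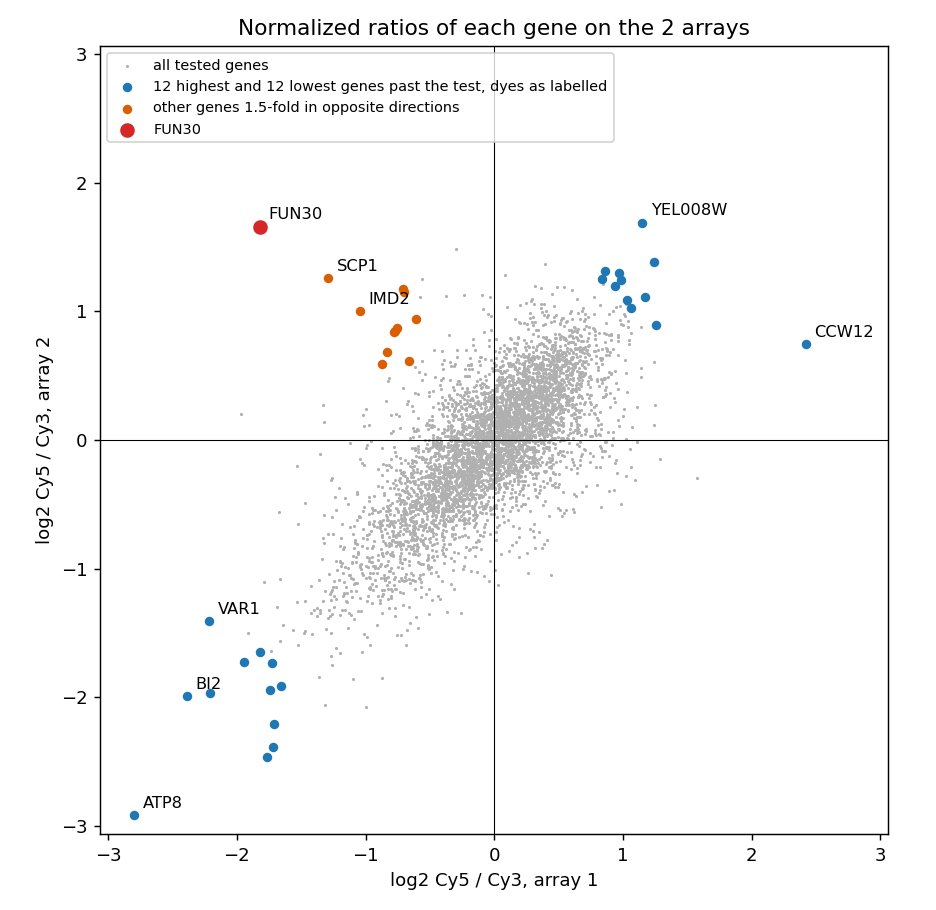
Normalized log2 ratio of Cy5 to Cy3 of each tested gene on array 1 (horizontal) and array 2 (vertical), 1 point per gene. Most genes lie along the rising diagonal (r = 0.72), while FUN30 lies at -1.82 and 1.66.

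With the dyes as labelled, CCW12, which encodes a cell wall mannoprotein, had the highest mean log2 ratio in the RNA labelled fun30 null, at 1.58 ± 0.36 (moderated SE, n = 2 arrays). Its ratio of Cy5 to Cy3 was 2.42 on array 1 and 0.74 on array 2, and its mean with array 2 turned 0.84 ± 0.64. BI2, a mitochondrial transcript, had the lowest mean of the genes above background in both dyes, at -2.19 ± 0.15, or -0.20 ± 0.80 with array 2 turned. ATP8, the mitochondrially encoded ATP synthase subunit, was not above background in Cy5 and was lower by at least 2.61-fold. In all, 513 genes were higher and 773 lower at an adjusted p under 0.05 by limma, so 39.9% of calls were higher. When both dyes had to be above background, 48.0% of calls were higher, and 303 of the 1286 genes were not tested. The excess of lower calls thus depends in part on genes dim in 1 dye. The directions of all calls hold only if the labels of both arrays are right, which FUN30 contradicted. With array 2 turned none of the 1286 genes passed.

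The other 11 of the 12 highest genes were YEL008W (1.42), SNA4 (1.31), PST1 (1.14), CCW14 (1.13), WBP1 (1.11), CFD1 (1.09), MMO1 (1.08), MCH4 (1.07), RBH2 (1.06), YFL006W (1.05) and MGR1 (1.05). PST1 and CCW14 encode cell wall proteins, WBP1 a subunit of the oligosaccharyl transferase, CFD1 a factor of iron-sulphur cluster assembly and MGR1 a subunit of a mitochondrial protease complex. Their SEs ran from 0.13 to 0.17, and the adjusted p of all 12 from 0.00618 to 0.0255. The 12 named lower genes were BI2, ATP8, COX9 and VAR1 with YMR046C (-2.11), VAS1 (-2.09), YPR158C-D (-2.05), ASN1 (-1.96), CTR1 (-1.83), RPA135 (-1.78), ACC1 (-1.73) and ANB1 (-1.73). Their SEs ran from 0.13 to 0.21, and their adjusted p from 0.00180 to 0.00660. VAS1 encodes valyl-tRNA synthetase, ASN1 an asparagine synthetase, CTR1 a copper transporter, RPA135 a subunit of RNA polymerase I and ACC1 acetyl-CoA carboxylase. COX9 and VAR1 were like ATP8 not above background in Cy5 on either array, so their folds are bounds of at least 2.40 and 2.21 in favour of the RNA labelled wild type. Cy5 was the weaker dye on both arrays, and nearly all such bounds favour the RNA labelled wild type. YMR046C and YPR158C-D belong to Ty elements with near-identical copies, which the probes cannot be assumed to tell apart.

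A fold threshold that needs no estimate of spread gave 168 genes at least 1.5-fold higher and 421 at least 1.5-fold lower on both arrays, with 12 that passed it in opposite directions. If the arrays were independent, 38.0, 87.4 and 115.6 such genes would be counted. At 2-fold the counts were 6, 95 and 3.

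The mitochondrial genome was the only 1 of 33 gene lists past the set test with the dyes as labelled (median log2 ratio -0.48, camera adjusted p = 0.0122). Its adjusted p was 0.986 with an estimated correlation. The call was also lost with background subtraction, median centring and the deposited values, while chaperones and ribosomal proteins gained calls under other processing. Of its 22 measured transcripts, 11 were lower and 0 higher, among them ATP8, BI2 and VAR1. Adjusted over the list alone, 12 were lower and 3 higher.

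The genes of DNA repair and of chromatin, closest to what is known of Fun30, had single members past the test, and none of their lists passed the set test. Over all 5036 tested genes 773 were lower and 513 higher, and the counts of members are to be read beside that share. Of 23 measured genes of end resection and break repair, RFA2 (0.71), MRE11 (0.63) and MMS4 (0.54) were higher and RFA1 (-1.12) was lower in the RNA labelled fun30 null. Of 12 checkpoint genes (median -0.27, percentile 4.67 of random lists) 3 were lower, RAD53 (-0.76) among them, and of 13 damage-induced genes 2 were higher and 2 lower, with UBI4 at -1.38 and RNR3 at -0.94. Of 11 Snf2-family remodellers 3 were higher, with SNF2 at 0.86 and CHD1 at 0.76, and 2 were lower. Of 21 silencing factors SIR2 (-0.80) was lower and RIF2 (0.60) higher. Among 6 probes of the mating-type cassettes, HMLALPHA2 (0.74) and HMRA2 (0.73) were higher. MATALPHA1 and HMRA1 were not above background in Cy5 on either array, with a bound of at least 1.10-fold lower for MATALPHA1 and none for HMRA1. The cassettes share sequence, so their probes cannot be assumed to be specific. Of 11 histone genes 4 were lower and 0 higher, HTB2 (-1.03) and HTA2 (-0.97) most, with a median of -0.39 at percentile 1.36 of random lists. Adjusted over the list alone, the counts were the same for these lists, except for 5 lower histone genes. The adjusted p of these lists ran from 0.238 for the histones to 0.979 for the damage-induced genes.

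Of the 5 measured neighbours of FUN30 on chromosome I, TPD3 (-1.14 ± 0.14, SE) and LDS1 (-0.59 ± 0.15) were lower and CCR4 (0.72 ± 0.14) was higher in the RNA labelled fun30 null (limma adjusted p = 0.00731, 0.0361 and 0.0174, n = 2 arrays). ATS1 (0.39) and FUN26 (0.36) did not pass the test. Adjusted over the list alone, 3 were higher and 2 lower, and the list of 5 did not pass the set test (adjusted p = 0.971). All 5 lay between -0.11 and 0.19 with array 2 turned. The strain markers LYS2 (0.64), HIS3 (0.30) and MET17 (0.20) were measured, and LYS2 passed the test (adjusted p = 0.0328, list adjusted p = 0.417).

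Of 135 ribosomal protein genes 29 were lower and 7 higher, with RPL15B at -1.71 and RPL6A at -1.54, and of 65 ribosome biogenesis genes 12 were lower and 7 higher, with RPA135 and EBP2 (-1.42) lowest. Many ribosomal proteins are encoded by gene pairs of nearly the same sequence, whose values may be mixed. Of 20 chaperone genes 9 were lower, HSP82 (-1.69) and YDJ1 (-1.26) most, and 1 was higher. Of 32 genes induced by environmental stress 8 were lower, with SSA4 at -0.97 and UGP1 at -0.96, and 3 were higher. Of 40 genes of respiration and the citric acid cycle 6 were lower, with COX9 and ATP1 (-1.06) first, and 3 higher. Of 20 genes of glycolysis and fermentation 3 were lower, with ADH2 at -1.37 and PFK1 at -1.32, and 1 was higher. Of 45 amino acid biosynthesis genes 8 were lower, with ASN1 and LEU4 (-1.30) first, and 2 higher. None of these lists passed the set test (adjusted p from 0.136 for the chaperones to 0.971). Over all 5036 genes 773 were lower and 513 higher, and the lower counts of respiration and of glycolysis lay near that share. Adjusted over the list alone, 31 ribosomal protein genes were lower and 8 higher, and the other counts here were the same.

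The remaining lists did not pass the set test either. Their counts of members stand beside 773 lower and 513 higher of all 5036 genes. Of 48 genes of subtelomeric families 6 were lower, COS2 (-1.44) and COS4 (-1.37) most, and 1 higher. Of 24 ergosterol genes 5 were lower, with ERG20 at -1.28, and 4 higher, and of 26 cell wall genes 5 were lower, with GSC2 at -0.89, and 3 higher, with PST1 first. In the iron regulon 3 of 17 were higher and FRE5 (-0.62) was lower, in the phosphate regulon CTF19 (0.57) was higher and PHO81 (-0.79) lower of 13, and in the zinc regulon FET4 (0.54) was higher of 7. Of 17 sulphur genes MET22 was lower at -1.19. Of 12 hexose transporters none passed, with HXT1 at -0.51 and HXT5 at -0.44. Of 15 genes under nitrogen catabolite control MEP3 (-0.74) was among 2 that were lower and UGA1 (0.59) was higher, and of 8 gluconeogenesis and fatty acid oxidation genes POX1 (-0.66) was lower. Of 24 G1/S genes 4 were lower, with GIN4 at -0.88, and 3 higher, and of 27 G2/M to G1 genes 5 were lower, with ASH1 at -1.05. MFA1 (0.59) was higher of 3 a-cell genes, AGA1 (0.98) was among 2 higher and FUS3 (-0.80) among 2 lower of 12 pheromone genes, none of 10 meiosis genes passed, and FMP16 (-0.78) and GRE1 (-0.62) were among 3 lower of 10 stationary-phase genes. MET22, GIN4 and FUS3 were not well above background in Cy5, with bounds of at least 2.00, 1.46 and 1.25. The adjusted p of these lists ran from 0.286 for the zinc regulon to 0.979 for the sulphur genes. Adjusted over the list alone, 5 genes of subtelomeric families were lower and 0 higher, 7 ergosterol genes lower and 4 higher, 5 cell wall genes lower and 6 higher and 4 G1/S genes lower and 4 higher, and the other counts were the same.

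**Figure D2:**
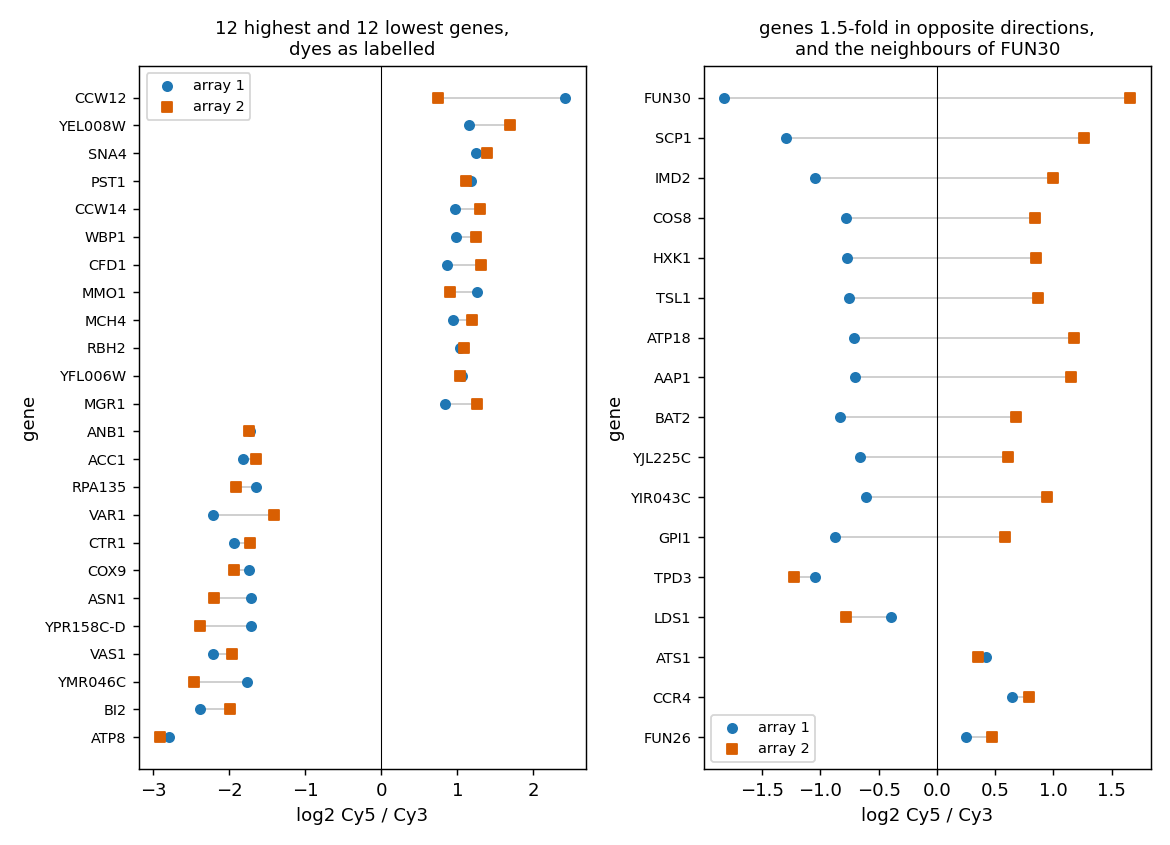
Normalized log2 ratio of Cy5 to Cy3 of named genes on array 1 (circles) and array 2 (squares). On the left are the 12 highest and 12 lowest genes with the dyes as labelled, with ATP8, COX9 and VAR1 near background in Cy5, and on the right FUN30 and the other genes 1.5-fold in opposite directions on the arrays, with the 5 neighbours of FUN30.

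With array 2 turned, the reading in which FUN30 is lower in the null on both arrays, FUN30 and 11 other genes were at least 1.5-fold lower on both arrays by their ratios. SCP1, which encodes an actin-bundling protein, had a mean log2 ratio of -1.28 ± 0.39 (SE, n = 2 arrays). IMD2, an IMP dehydrogenase gene, was at -1.02 ± 0.39. ATP18 (-0.94), AAP1 (-0.93), COS8 (-0.81), HXK1 (-0.81), TSL1 (-0.81), YIR043C (-0.77), BAT2 (-0.76) and YJL225C (-0.64) followed, and 0 genes were 1.5-fold higher on both arrays. ATP18 encodes an ATP synthase subunit, HXK1 a hexokinase, TSL1 a subunit of trehalose synthase and BAT2 a branched-chain aminotransferase. GPI1 also met the threshold, but it was not above background in Cy5 on either array, and no fold is given for it. COS8 and YJL225C belong to subtelomeric families with related copies.

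None of these 12 passed the test in that reading: limma called 0 genes, with 7 at an unadjusted p under 0.05, all lower, and eBayes with trend and robust also called 0. At 2-fold, 3 genes were lower on both arrays (FUN30, SCP1 and IMD2).

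As a set, the genes of respiration and the citric acid cycle were lower with array 2 turned (median -0.24, camera adjusted p = 9.85e-09, but adjusted p = 0.825 with an estimated correlation). The correlation estimated for this list was 0.04. Among the 11 gene lists past the test in this reading it ran from -0.08 (damage-induced genes) to 0.20 (amino acid biosynthesis). With 1 residual degree of freedom such an estimate cannot tell whether the preset correlation suits a list. The adjusted p of 9.85e-09 therefore rests on the preset correlation. The version with an estimated correlation could hardly pass any list, so 0.825 does not show that correlation removed the call. Of 40 measured, 36 had a mean below 0, 15 were lower on both arrays and 1 was higher on both. Over all 5036 genes 23.6% had the same sign on both arrays in this reading. The counts of genes lower or higher on both arrays, here and below, are to be read beside that share. The list's median log2 ratio of Cy5 to Cy3 was -0.16 on array 1 and 0.29 on array 2. QCR10 (-0.55), ATP4 (-0.48), ATP14 (-0.45) and COX4 (-0.44), subunits of the respiratory chain and the ATP synthase, had the lowest means. The mitochondrial genome passed with a median of -0.15 (adjusted p = 0.0200, but adjusted p = 0.825 with an estimated correlation), with OLI1 at -0.44. Only 2 of its 22 measured genes were lower on both arrays in this reading, and 0 were higher on both. That list was past the test in both readings, and without array 1 its turned median was 0.50.

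Ribosomal protein genes were lower as a set (median -0.09, adjusted p = 0.00142, but adjusted p = 0.825 with an estimated correlation), with RPL7B at -0.73. Of 135, 104 had a mean below 0, 30 were lower on both arrays and 6 higher on both. Genes induced by environmental stress were lower (median -0.07, adjusted p = 0.0277, but adjusted p = 0.825 with an estimated correlation), with HXK1, TSL1 and GLK1 (-0.68) first. They were split, with 17 below and 15 above 0. Genes of subtelomeric families were lower (median -0.07, adjusted p = 0.00521, but adjusted p = 0.825 with an estimated correlation), led by COS8 and by YRF1-1 (-0.56) among the lower members, while AAD15 was at 0.70. In Cy5 over Cy3 the median of these families was -0.13 on array 1 and 0.13 on array 2. That of the stress genes was -0.09 and 0.12.

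Higher as sets with array 2 turned were amino acid biosynthesis (median 0.11, adjusted p = 0.00142), with ARG1 at 0.68 and LYS4 at 0.55, and the iron regulon (median 0.10, adjusted p = 0.00521), with FIT3 at 0.93 and FIT2 at 0.56. Both had an adjusted p = 0.825 with an estimated correlation. FIT2 and FIT3 encode cell wall proteins that retain iron carriers. The chaperones were higher (median 0.12, adjusted p = 0.00581, but adjusted p = 0.825 with an estimated correlation), with AHA1 at 0.74 and CPR6 at 0.47, both co-chaperones of Hsp90. So were glycolysis and fermentation (median 0.10, adjusted p = 0.0153), with FBA1 at 0.48, damage-induced genes (median 0.12, adjusted p = 0.0387), with HUG1 at 0.61 and PLM2 at 0.51, and ribosome biogenesis (median 0.07, adjusted p = 0.0432), with NOC3 at 0.37. These 3 lists also had an adjusted p = 0.825 with an estimated correlation. Glycolysis and ribosome biogenesis also lost their calls after regression on the as-labelled ratio and intensity (medians 0.08 and 0.05, adjusted p = 0.170 and 0.0730). No single member of any list passed the test in this reading, over all genes or adjusted over the list alone. The iron regulon had a median log2 ratio of Cy5 to Cy3 of 0.27 on array 1 and -0.07 on array 2, and the damage-induced genes 0.09 and -0.22, so their sizes differed between arrays. Without array 1 the ribosomal protein median was 0.01 and that of glycolysis -0.07, and without array 2 the medians of ribosome biogenesis, chaperones and amino acid biosynthesis were -0.06, -0.14 and -0.06.

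The other 22 lists did not pass with array 2 turned. The 23 genes of end resection and break repair had a median of -0.04 (camera mean direction up, adjusted p = 0.907), with RAD10 at 0.34. The 12 checkpoint genes had a median of 0.04, with DDC1 at 0.53 and RAD9 at 0.43, and the 21 silencing factors -0.04, with SIR4 at 0.60. The adjusted p of the 22 lists ran from 0.0805 for the hexose transporters to 0.960 for the silencing factors.

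**Figure D3:**
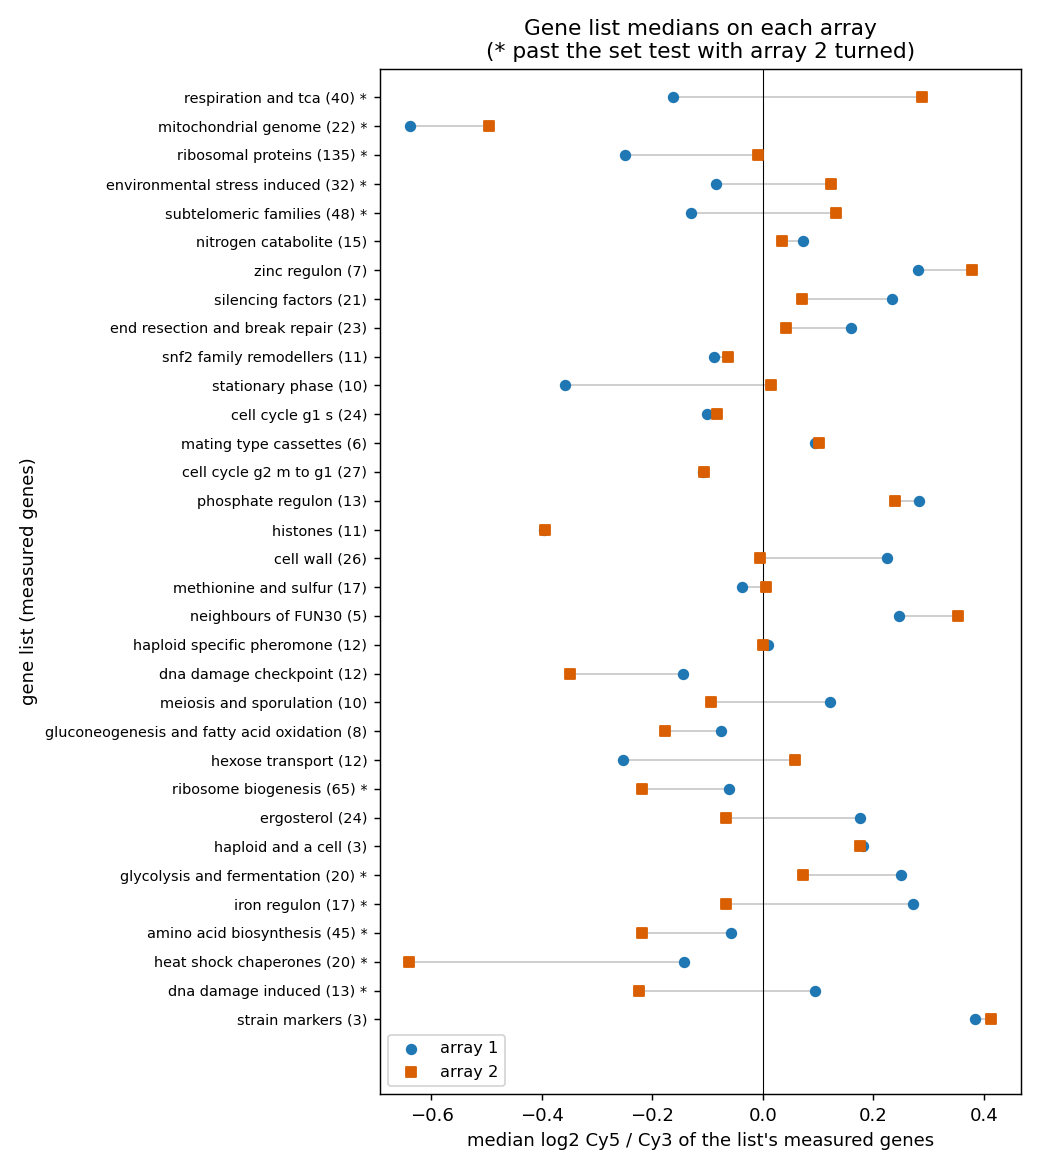
Median log2 ratio of Cy5 to Cy3 of each gene list on array 1 (circles) and array 2 (squares), with the number of measured genes in brackets and a star where the list passed the set test with array 2 turned. Respiration lies at -0.16 on array 1 and 0.29 on array 2, while the mitochondrial genome lies below 0 on both.

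Along the genome, genes near chromosome ends passed the set test when array 2 was turned, and no whole chromosome did in either reading. The 126 measured genes among the last 5 reading frame numbers of each arm had a median of -0.10 on array 1 and 0.10 on array 2 in Cy5 over Cy3. Turned, their median was -0.07 (camera adjusted p = 7.56e-07), and 81 of 126 had a mean below 0, 32 of them lower on both arrays against 13 higher on both. The adjusted p was 0.167 with an estimated correlation. Without members of the listed families, 95 genes kept a median of -0.07 (adjusted p = 2.44e-05). Without genes that have only a systematic name as well, the 42 left had a median of -0.01 (adjusted p = 0.854). With the dyes as labelled their median was 0.03 (adjusted p = 0.962), with 5 genes higher and 10 lower, or 3 and 8 when adjusted over the list alone. The 131 genes nearest the centromeres did not pass in either reading (adjusted p = 0.962 and 0.949). Among them 21 were higher and 23 lower with the dyes as labelled, or 24 and 27 when adjusted over the list alone. Over all 5036 genes 513 were higher and 773 lower. Medians of the 16 chromosomes ran from -0.11 to 0.15 with the dyes as labelled and from -0.03 to 0.03 turned, with 0 past the set test.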

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

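Some Arabidopsis control spots, which the comparisons above do not use, were counted as above background, while empty spots were not. On array 1, 21.9% of the 64 control spots were above background in at least 1 dye, and on array 2 9.38% were. Of the 704 empty or unnamed spots, 0 were above background on either array. Whether control RNA was added to the labelled samples is not given in the sources used here.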

How the results depend on the processing

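Runs that combine a turned array 2 with another change were chosen after seeing the data, and the others before. With the dyes as labelled, the correlation between arrays lay between 0.70 and 0.74 under every change of background, normalization, foreground, filter or source of ratios. FUN30 kept opposite signs on the arrays under all of these, except that it was not tested when both dyes had to be above background. Chromosomes had 0 calls in every run. The 10 and 30 kb windows were not run, since no coordinates could be used. No paired analysis was possible because each array already pairs the strains. Dim spots limit depth most in Cy5 of array 2.

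With the dyes as labelled, background subtraction gave 808 genes past adjusted p 0.05, 923 genes 1.5-fold the same way on both arrays and 0 gene lists. The deposited values gave 901 genes 1.5-fold the same way and 0 lists. Median centring gave 0 lists, mean foreground 2, and a filter on both channels 3. The gained calls were chaperones with mean foreground (adjusted p = 0.0388) and chaperones (0.0257) and ribosomal proteins (0.0228) with the filter, all lower. An adjusted p of 0.10 gave 1946 genes, duplicateCorrelation over duplicate spots 2082, and a 2-fold threshold 101 genes the same way. An estimated correlation and fry each gave 0 lists. Single arrays, with no second one to pass, held 1077 to 1127 genes at 1.5-fold. FUN30 was 1.66 without replicate 1 and -1.82 without replicate 2. Beyond these constructions, the cause was not tested.

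Turning array 2 gave r = -0.72, 0 genes past the test, 12 genes 1.5-fold the same way, 11 gene lists and 1 regional list. Among lists past the test in at least 1 reading, the direction of the camera test reversed, with the turned medians in brackets, for damage-induced genes (0.12), subtelomeric families (-0.066), ribosome biogenesis (0.065), chaperones (0.12), respiration (-0.24), amino acid biosynthesis (0.11) and the subtelomeric region (-0.074). The median of the damage-induced genes was above 0 in both readings. The median of environmental stress fell below 0 (-0.07) while its tested direction stayed down. Of the named genes carried through the alternatives, turning reversed among those called higher YEL008W (-0.27), SNA4 (-0.072), CCW14 (-0.17), WBP1 (-0.13), CFD1 (-0.23), MCH4 (-0.13), RBH2 (-0.029), MGR1 (-0.20), CCR4 (-0.074), RFA2 (-0.063), MRE11 (-0.046), CHD1 (-0.031), HMRA2 (-0.039), CTF19 (-0.12) and FET4 (-0.049). Among those called lower it reversed ATP8 (0.060), YMR046C (0.35), YPR158C-D (0.33), ASN1 (0.25), COX9 (0.10), RPA135 (0.13), ANB1 (0.0042), TPD3 (0.091), LDS1 (0.19), RFA1 (0.13), RAD53 (0.21), MRC1 (0.063), UBI4 (0.12), HTB2 (0.00089), HTA2 (0.061), EBP2 (0.23), SSA4 (0.12), UGP1 (0.022), HSP82 (0.37), PFK1 (0.046), MET22 (0.021), LEU4 (0.019), ERG20 (0.081), GSC2 (0.32), GIN4 (0.054), FUS3 (0.24), FMP16 (0.0095), POX1 (0.029) and MEP3 (0.29). None of these genes was past the test once turned, and every turned mean was smaller than its SE, so these signs carry no direction.

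With array 2 turned, FUN30 had the smallest p in every run that tested it, and 0 genes were called in any. Since FUN30 prompted the turning, that rank restates its opposite ratios. Background subtraction gave 33 genes 1.5-fold the same way on both arrays and 6 lists, and the deposited values 24 genes and 7 lists. A 2-fold threshold gave 3 genes. An estimated correlation gave 0 gene lists and 0 regional lists, and fry 0 gene lists, with an adjusted p of 0.433 for the subtelomeric region. Single arrays held 1077 to 1127 genes at 1.5-fold. On single arrays the list medians ran from -0.25 to 0.0096 for ribosomal proteins, -0.073 to 0.25 for glycolysis, -0.64 to 0.50 for the mitochondrial genome, -0.062 to 0.22 for ribosome biogenesis, -0.14 to 0.64 for chaperones and -0.057 to 0.22 for amino acid biosynthesis. The respiration list and the subtelomeric region stayed past camera at its preset correlation under each change of background, normalization, foreground, filter or source of ratios. The cause of the other moves was not tested.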

Other observations

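The tests chosen only after the result was seen were both tests on the opposite ratios of FUN30, its use against the labelled direction, the tests on subtelomeric families and growth stage, and every run that combines a turned array 2 with another change. In that turned reading the 12 hexose transporters did not pass the test (adjusted p = 0.0805), with 7 of 12 above 0, a median of 0.06 and a mean of -0.13. Their lowest members, HXT7 (-0.85) and HXT6 (-0.75), are near-identical copies. When genes had to be above background in both dyes, the list's median was -0.30 (adjusted p = 0.000224), and with mean foreground it was 0.03 (adjusted p = 0.0205), so its sign is not settled. In the zinc regulon ZRT1, a zinc transporter gene, was at -0.57. Histone genes HTA1 and HTB1 were at 0.36 and 0.27, while the median of the 11 histone genes lay near 0. Probes ending in -R followed their partners in both parts of the ratios, with r = 0.83 over 82 pairs for the mean as labelled and 0.67 for the mean with array 2 turned.

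FUN30 was low in Cy5 on array 1 and high in Cy5 on array 2. Spot noise in a dim probe is argued against by the 500 genes nearest in intensity, of which 0 lay as far out in opposite directions. The 259 genes with as few spots above background had a largest difference between arrays of 1.46, against 3.48 for FUN30. They were not matched on signal, and FUN30 read 923 and 994 in Cy3 on array 1, over 260 and 294. The background offset draws ratios of dim spots toward 0, so their smaller range may be partly built in. A candidate explanation is that the dyes of array 2 were the other way round from its labels. That 0 of the other 5035 genes lay as far out in that direction restates what prompted it, and no second probe of FUN30 was on the arrays, so it stays open. A swap of the 2 RNAs before labelling would look the same and stays open too.

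The ratios shared by both arrays in dye terms (r = 0.72) gave the 1286 calls with the dyes as labelled. A strain difference with the dyes as labelled on both arrays is argued against by FUN30, which was at 1.66 on array 2. Only 1 spot there was above background, but of the 259 other genes with as few such spots 0 were as high, the highest at 1.37. The 1.66 is the mean of 2.42 for the spot above background and 0.90 for the other, which lay below 1.37. The contrast with these genes therefore rests on 1 spot. A dye or probe effect that does not depend on the strain may give ratios shared by both arrays. The control probes could have tested it, but 2 were above background on both arrays, too few for a correlation, so the effect stays open.

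The subtelomeric region and the respiration genes were lower with array 2 turned (adjusted p = 0.167 and 0.825 with an estimated correlation). A dye effect left over after turning was checked by regression on the as-labelled ratio and the intensity. Both lists stayed past the test, with 6.82e-07 as the larger camera adjusted p. The regression had little to remove. The SDs of the 2 arrays were nearly equal (0.48 and 0.50), which leaves turned and as-labelled means nearly unrelated, and loess had already taken out intensity trends. Passing it therefore does not argue against a leftover dye effect. The regression cannot remove a dye effect that differs between arrays gene by gene, which stays open. The mitochondrial genome, below 0 in Cy5 over Cy3 on both arrays, also stayed past camera after regression (adjusted p = 0.0165). Cross-hybridisation within the multi-copy subtelomeric families stays open, since the region passed without the listed families (95 genes, adjusted p = 2.44e-05) but not without genes that have only a systematic name, some of them further copies (42 genes, median -0.01, adjusted p = 0.854). Growth stage of the 2 cultures cannot be told apart from the strain, as only 8 gluconeogenesis and fatty acid oxidation genes were measured (median 0.057), fewer than the 10 asked for by a rule set when that number was known, and each strain had 1 culture. An effect of the loss of Fun30 itself was not tested apart from it.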
